A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

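The labels describe poly(A) RNA of Saccharomyces cerevisiae strain S288C, grown to log phase in rich medium, folded and cut with RNase V1 at 23, 30, 37, 55 or 75 °C, with 2 biological replicates per temperature. Fragments were cloned with a small RNA kit and sequenced on the SOLiD platform, per the labels' protocols. The deposited table holds raw counts of cut sites at each position of each transcript, with 1 column per library, per the file headers and the values, which are whole numbers. The genome build is sacCer2, per the submitters' processing notes; the aligner, its settings and the treatment of reads that fit several places are not given in the sources used here. All 10 count columns were used, and each was tied to its sample by the column name that the sample's description gives. Reads that fit more than one gene can be dropped, split or counted in each copy, so counts of duplicated genes can differ between libraries if this step did.

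Of 4842 entries, 4561 matched the RefSeq gene table of assembly R64 by locus tag and 85 by symbol, and this table was used for names, RNA classes and coding lengths only. Of the rest, 189 are tRNA entries, 1 is another yeast identifier and 6 (HA479, HA5, HA704, HT, p4 and p9) match no yeast gene. To avoid counting repeated entries, 172 entries were left out. Of these, 161 were identical at every position to an earlier entry, and 160 of them are tRNAs. The others were 10 rRNA entries that copy or contain others, and the short form of 1 snRNA entry. Near-identical gene copies were kept, so a read counted in several copies would still be counted more than once. The 6 entries without a match were left out of tests, and they held 1.46% to 2.52% of the counts per library. They served for 1 alternative scaling, which had been set for added control RNAs; using it on these entries, whose identity is not given, was decided after the file was seen. Depth ran from 18562306 to 28592360 counts per library. The highest depths, 28592360 and 28441394, are those of 23 °C replicate 1 and 37 °C replicate 2, and reads counted in more than 1 gene copy would raise them. Labelled replicates differed by more than counting noise, with a chi-square per degree of freedom over transcripts from 31.9 to 1321; other pairs were not tested, and all libraries were kept as separate samples.

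Counts were summed per transcript and tested in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with TMM scaling and filterByExpr, which kept all 4664 transcripts. Fits used all 10 libraries, either with 1 coefficient per temperature (75 °C against 23 °C and the 4 steps between neighbours) or with a slope on the labelled temperature in log2 units per 10 °C. The adjusted p is that of Benjamini and Hochberg, with a threshold of 0.05, and all of these tests are two-sided. Gene lists were tested by camera in limma 3.58.1 on the slope, with a preset correlation of 0.01 and with an estimated one, over the 17 lists with 5 or more tested members. The same lists were also tested by fry, another list test of limma. The 4 snRNA and 4 rRNA entries are too few, and lists of mitochondrially encoded genes and of transposons had 0 tested members. Windows of 50 nt with 100 or more counts over all libraries were tested for a slope with the transcript total in each library as the offset. Shares were correlated with the labelled temperature by permutation, 100000 draws with 10 libraries and exact with fewer, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Agreement over positions was set to use untransformed counts, and log2(count + 1) at positions with 200 or more counts over all libraries was added after the data were seen. CPM values are TMM-scaled. Levels and SD are over the libraries named beside them, and SE come from the edgeR fit.

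Named genes were fixed before the data were examined as the 10 largest rises and falls at 75 °C that passed both the pairwise and the slope test, the 2 members of each list with the most counts and the 2 with the smallest p for the slope, and windows past the threshold with 1000 or more counts. No transcript and no window met the first and the last part, so the leading transcripts of the slope are named by smallest p, after their values were seen. Alternatives set at that time were total-count scaling, DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter, scaling on mRNAs alone or on control RNAs, an estimated correlation for lists, the replicate number as a block, each library left out in turn, other windows and count minimums, library scaling for windows, equal weights per transcript, positions with 10 or more counts for agreement, and, for class shares, no 100 highest positions and no libraries farthest from the median temperature. Leaving out 23 °C replicate 1 together with 37 °C replicate 2, splitting the class of other entries, leaving out the farthest libraries for codon shares and the density at transcript ends were added after the data were seen. Shares by untranslated region and profiles around start and stop codons were not run, because the boundaries of coding sequence on these transcripts were not used here. The tests were tested on simulated data drawn from the real means of 4664 transcripts, with 200 transcripts changed. At a coefficient of variation of 0.2 the slope test recovered 80% of transcripts changed 2-fold and 100% of those changed 3-fold. Every simulated transcript had the same spread, and the differences between single real libraries were not simulated.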

Results

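RNase V1 cleaves base-paired and stacked stretches of RNA, so the number of sequenced fragments that start at a position reports how often that position was cut as double-stranded RNA. Poly(A)-selected RNA of log-phase budding yeast (strain S288C) was folded and cut at 5 temperatures, with 2 biological replicates at each, which gives 10 libraries. Samples labelled 23, 30, 37, 55 or 75 °C were set against each other. The question was which RNAs, and which parts of them, took a smaller or larger share of the cuts as the temperature rose. Counts were scaled within each library or transcript, so a change in cutting common to all RNAs would not be seen. The share of a transcript also depends on its amount, so a rise in share is not by itself a rise in cutting. After repeated entries were removed, each library held between 18562306 and 28592360 counts on 4670 entries, 4558 of them mRNAs. The mRNAs had 1.54 to 2.97 counts per position, and 43.2% of all positions had no count in any library.

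Counts per mRNA correlated more closely between libraries than counts per position. Over 4558 mRNAs, log2 CPM correlated at a mean r of 0.966 ± 0.028 (SD, n = 5 pairs) between libraries of one labelled temperature and at 0.965 ± 0.020 (SD, n = 40 pairs) between libraries of different labelled temperatures. Over all positions, untransformed counts gave a mean r of 0.691 ± 0.297 (SD, n = 5 pairs) within and 0.631 ± 0.244 (SD, n = 40 pairs) between labelled temperatures. On the log2 scale over the 104341 positions with 200 or more counts, a measure chosen after the data were seen, libraries of one labelled temperature had a mean r of 0.50 ± 0.36 (SD, n = 5 pairs). This ran from -0.0441 for the pair labelled 37 °C to 0.821 for the pair labelled 55 °C, and the mean between labelled temperatures was 0.474 ± 0.284 (SD, n = 40 pairs). In each measure the means differ by far less than their SD, and these correlations run across transcripts or positions, which are not independent replicates. The libraries labelled 23 °C replicate 2 and 30 °C replicate 1 were closest to each other (r = 0.857), and so were 30 °C replicate 2 and 75 °C replicate 1 (r = 0.833), 37 °C replicate 1 and 75 °C replicate 2 (r = 0.819), and 23 °C replicate 1 and 37 °C replicate 2 (r = 0.757). The library 55 °C replicate 1 was closest to its labelled replicate (r = 0.821), which was itself closest to 23 °C replicate 2 (r = 0.822). Positions were kept by their total over all 10 libraries, so positions high only in 23 °C replicate 1 and 37 °C replicate 2 can be among them. On rRNA positions alone, the labelled pairs ran from r = 0.592 (37 °C) to r = 0.966 (23 °C). Over all entries the pair labelled 23 °C had r = 0.303. Because replicates of one label differed this much, each value below is given for libraries as labelled.

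**Figure D1:**
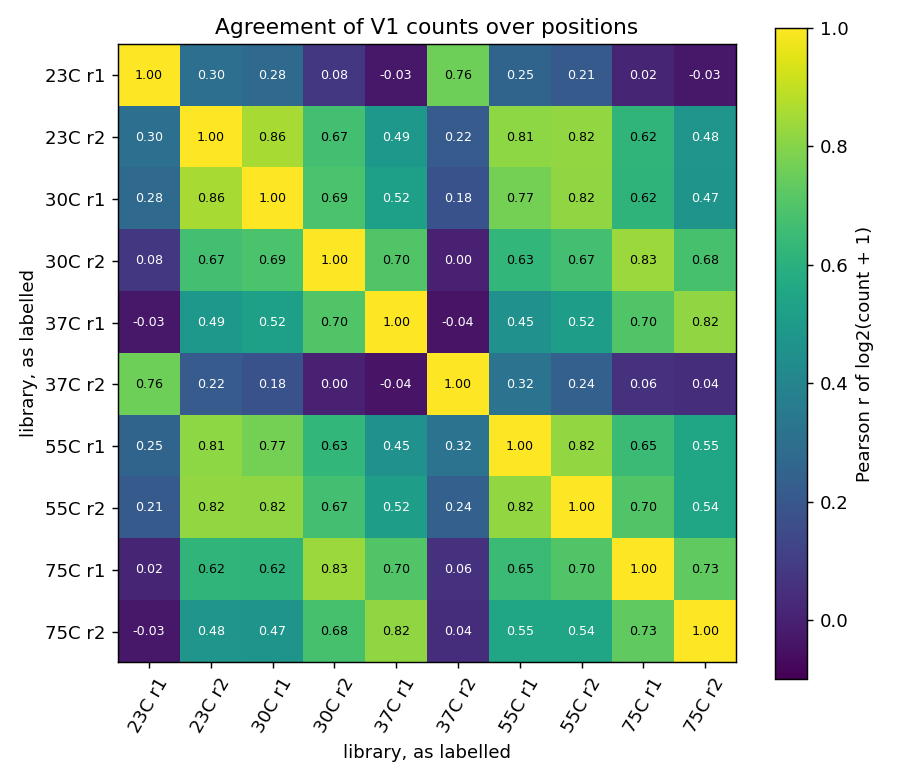
Pearson r of log2(count + 1) over 104341 positions for each pair of the 10 libraries, with the libraries as labelled on both axes and r as colour and number. The pair labelled 37 °C has an r of -0.0441, whereas 37 °C replicate 1 and 75 °C replicate 2 reach 0.819.

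The comparison of the libraries labelled 75 °C with those labelled 23 °C asked which transcripts carried a larger or smaller share of the cuts at the highest temperature. SEN1, a helicase of transcription termination, had 72.4 and 80.3 CPM at 75 °C against 40.9 and 38.8 CPM at 23 °C, a log2 difference of 0.94 ± 0.14 (SE, n = 2 against 2). GLT1, the glutamate synthase, had a log2 difference of 0.99 ± 0.14 (SE). ERD2, the receptor that returns proteins to the endoplasmic reticulum, had 100 and 90.9 CPM at 75 °C against 177 and 168 CPM at 23 °C, a log2 difference of -0.85 ± 0.13 (SE). RPL17A, a protein of the large ribosomal subunit, had a log2 difference of -1.17 ± 0.26 (SE). None of these passed the test. EdgeR's quasi-likelihood test called 0 of 4664 transcripts at a Benjamini-Hochberg adjusted p under 0.05, the smallest adjusted p being 0.116. An unadjusted p under 0.05 was found for 993, and DESeq2's Wald test called 314, of which 152 were higher and 162 lower. Scaling to the 6 entries that match no yeast gene gave 74 calls, 2 higher and 72 lower, with the median of all transcripts shifted by -0.127, and 2 transcripts passed without 75 °C replicate 1. On simulated data with a biological coefficient of variation of 0.2, the edgeR test recovered 60% of transcripts changed 2-fold and 98% of those changed 3-fold. The common value found here was 0.222, but the simulation gave every transcript the same spread. It also held no excess of gene copies in single libraries, so these percentages may overstate recovery in the real libraries. SEN1, GLT1 and ERD2 were chosen after their values were seen, since 0 transcripts met the rule for named genes in this comparison.

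The steps between neighbouring temperatures asked at which step transcripts changed. From 23 °C to 30 °C, SEN1 had a log2 difference of 0.16 ± 0.14 (SE) and FBA1, the glycolytic aldolase, one of -0.05 ± 0.21 (SE). At the step from 30 °C to 37 °C the spliceosomal snRNA LSR1 had a log2 difference of 0.74 ± 0.30 (SE), with 26.8 and 25.0 CPM at 30 °C and 46.4 and 40.0 CPM at 37 °C. The ribosome-associated chaperone genes SSB1 and SSB2 had the values 1.97 ± 0.90 and 2.18 ± 1.04 (SE) at this step, where SSB1 stood at 764 CPM in one 37 °C library and at 4992 CPM in the other. By edgeR, 0 of 4664 transcripts passed at each of the 4 steps. In the order of the steps, 2.55%, 8.36%, 2.25% and 4.70% of the transcripts had an unadjusted p under 0.05 (119, 390 and 219 at all but the step from 37 °C to 55 °C), and DESeq2's Wald test called 0, 5, 1 and 0. Without the library labelled 37 °C replicate 2, 129 transcripts passed between 37 °C and 55 °C. One passed between 30 °C and 37 °C without 37 °C replicate 2, 75 °C replicate 1 or 75 °C replicate 2, and 1 between 55 °C and 75 °C without 75 °C replicate 1. Scaling to the 6 entries that match no yeast gene gave 35, 11, 24 and 0 calls, with medians of all transcripts of -0.07, -0.20, -0.18 and 0.35. Total-count scaling gave 0 calls, with medians of 0.13, -0.28 and 0.25 at the 3 lower steps.

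A slope over all 10 libraries asked which transcripts changed steadily with the labelled temperature. SEN1 rose by 0.17 ± 0.02 (SE) log2 units per 10 °C, from 40.9 and 38.8 CPM at 23 °C through 52.1 and 55.5 CPM at 37 °C to 72.4 and 80.3 CPM at 75 °C (adjusted p = 0.0280). RPO31, the largest subunit of RNA polymerase III, rose by 0.13 ± 0.02, and GLT1 by 0.17 ± 0.03. ERD2 had a slope of -0.15 ± 0.03, YIP1, which acts in vesicle transport, one of -0.17 ± 0.03, and PML1, of a complex that retains unspliced RNA, one of -0.17 ± 0.03. In all, 121 of 4664 transcripts had an adjusted p under 0.05 by edgeR's quasi-likelihood test, 90 rising and 31 falling. There were 1078 at an unadjusted p under 0.05, and DESeq2's Wald test called 492 (262 rising, 230 falling). The 89 mRNAs that rose had a median length of 3656 nt and the 30 that fell one of 886.5 nt, against 1410 nt for all tested mRNAs. SEN1, RPO31, GLT1, ERD2, YIP1 and PML1 were chosen after their values were seen, from the 10 rising and 10 falling transcripts with the smallest p. The count of 121 fell to 0 under total-count scaling, under scaling to the entries that match no yeast gene, and without 23 °C replicate 1, 23 °C replicate 2, 30 °C replicate 1, 55 °C replicate 2 or 75 °C replicate 2. It stood at 40 without 55 °C replicate 1, 11 without 75 °C replicate 1, 212 without 30 °C replicate 2 and 411 without 37 °C replicate 1.

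Ribosomal protein mRNAs had the smallest camera p of all lists with the preset correlation for the slope on labelled temperature: 134 of 138 members had a negative slope, with a median of -0.12 log2 units per 10 °C. RPL17A fell by 0.20 ± 0.05 (SE; edgeR adjusted p = 0.0438), whereas RPL10 and RPS2, the members with the most counts among those listed by rule, had slopes of -0.09 ± 0.05 and -0.04 ± 0.04 that did not pass. One member, RPL17A, passed over all transcripts and 0 adjusted over the list alone by edgeR. Camera with its preset correlation gave the list an adjusted p of 2.34e-13 over 17 lists, and the adjusted p was 0.844 with an estimated correlation. By fry the adjusted p was 0.151 for this list, 0.169 for glycolysis and fermentation and 0.505 for tRNA. The smallest fry adjusted p of any list was 0.0699, for ribosome biogenesis, so none passed by fry. The list stood 0.999 and 0.924 log2 units above its mean in the libraries labelled 23 °C replicate 1 and 37 °C replicate 2, and between -0.47 and -0.02 in the other 8. Of all lists, 4 had a camera adjusted p under 0.05 with the preset correlation, against 1 without 23 °C replicate 1, 2 without 75 °C replicate 1 and 7 without 75 °C replicate 2. The name pattern fixed for this list also took RPP1, a subunit of RNase P.

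Genes of glycolysis and fermentation had 16 negative and 3 positive slopes among 19 members, with a median of -0.07. FBA1 had a slope of -0.09 ± 0.03 (SE), the pyruvate kinase gene CDC19 one of -0.12 ± 0.04 and the glucokinase gene GLK1 one of -0.24 ± 0.06, and none of them passed. Camera's preset correlation gave the list an adjusted p of 0.0288, and the adjusted p was 0.852 with an estimated correlation. The preset call was lost without 23 °C replicate 1 or 75 °C replicate 1, as was that of ribosome biogenesis. By edgeR, 0 members passed over all transcripts and 1 fell adjusted over the list alone. This list, too, stood 1.01 and 1.07 log2 units above its mean in 23 °C replicate 1 and 37 °C replicate 2. Without both of these libraries, a setting chosen after the data were seen, the preset adjusted p was 0.0221 for this list, 2.40e-08 for ribosomal proteins and 0.0206 for tRNA, and the call of ribosome biogenesis was lost. Among 54 genes of ribosome biogenesis, RRP5, UTP21, NOP4 and RPA190 rose, and 6 rose adjusted over the list alone. RRP5 rose by 0.11 ± 0.02 and UTP21 by 0.08 ± 0.02 (SE). RRP5, UTP21, NOP4 and RPA190 have 5379, 2878, 2144 and 5379 nt, above the median of 1410 nt for all tested mRNAs. NOP4 and RPA190 were named after their values were seen, and the list's camera adjusted p was 0.0344 with the preset correlation and 0.577 with an estimated one. The tRNA list, with 26 positive and 3 negative slopes among 29 entries, had an adjusted p of 0.0244 with the preset correlation and 0.917 with an estimated one. The preset value ran from 2.31e-09 without 75 °C replicate 1 to 0.818 without 75 °C replicate 2, and the call was also lost without 23 °C replicate 1 (0.0527), 30 °C replicate 2 (0.0784) or 55 °C replicate 1 (0.0613). The glutamate tRNA tE-UUC-B ranged from 70.2 CPM in 75 °C replicate 1 to 872 CPM in 37 °C replicate 2, and the pair labelled 75 °C had 70.2 and 722 CPM.

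The remaining lists had no camera adjusted p under 0.05 over all 10 libraries, either with the preset or with an estimated correlation. Without 75 °C replicate 2 the preset value was 0.0105 for histones, 0.0385 for oxidative phosphorylation, 0.0171 for amino acid biosynthesis and 0.00732 for snoRNA. Without 23 °C replicate 2 it was 0.0312 for histones, and without 37 °C replicate 1 it was 0.0491 for oxidative phosphorylation. Of 32 proteasome genes, RPN1 and RPN2 of the regulatory particle rose by 0.15 ± 0.03 and 0.13 ± 0.02 (SE). PRE2 and SCL1 of the core particle fell, PRE2 by 0.15 ± 0.03. RPN1 and RPN2 have 3262 and 2966 nt, and PRE2 and SCL1 have 1019 and 879 nt. Slope and length had a Spearman rho of 0.393 over mRNAs, so this split cannot be told apart from transcript length. Adjusted over the list alone, 3 of the 32 proteasome genes rose and 6 fell, and the list's camera adjusted p was 0.880. Genes of the nuclear-encoded oxidative phosphorylation list, with COX13 at a slope of -0.07 ± 0.02, had an adjusted p of 0.0808, and the 10 histone genes, with HHT2 at -0.14 ± 0.04, one of 0.0835. The chaperone list, with SSA3 at a slope of 0.13 ± 0.03 and YDJ1 at 0.11 ± 0.03, had an adjusted p of 0.880, and 2 members rose and 1 fell adjusted over the list alone. LYS2 of amino acid biosynthesis (4322 nt) rose by 0.09 ± 0.02, and SKI2, a helicase of the Ski complex (3988 nt), by 0.08 ± 0.02. The initiation factor FUN12 (3134 nt) rose by 0.11 ± 0.03, and the mitochondrial ribosomal protein gene RSM27 (499 nt) fell by 0.14 ± 0.03. The lists of LYS2, SKI2, FUN12 and RSM27 had camera adjusted p of 0.401, 0.643, 0.880 and 0.401. Of the exosome and Ski list, 3 rose and 2 fell adjusted over the list alone. The lists of the tricarboxylic acid cycle, ergosterol synthesis, cell wall, snoRNA and other noncoding RNA had 0.880, 0.953, 0.559, 0.401 and 0.880, and snR43, with a slope of -0.33 ± 0.06, was the 1 snoRNA that fell.

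**Figure D2:**
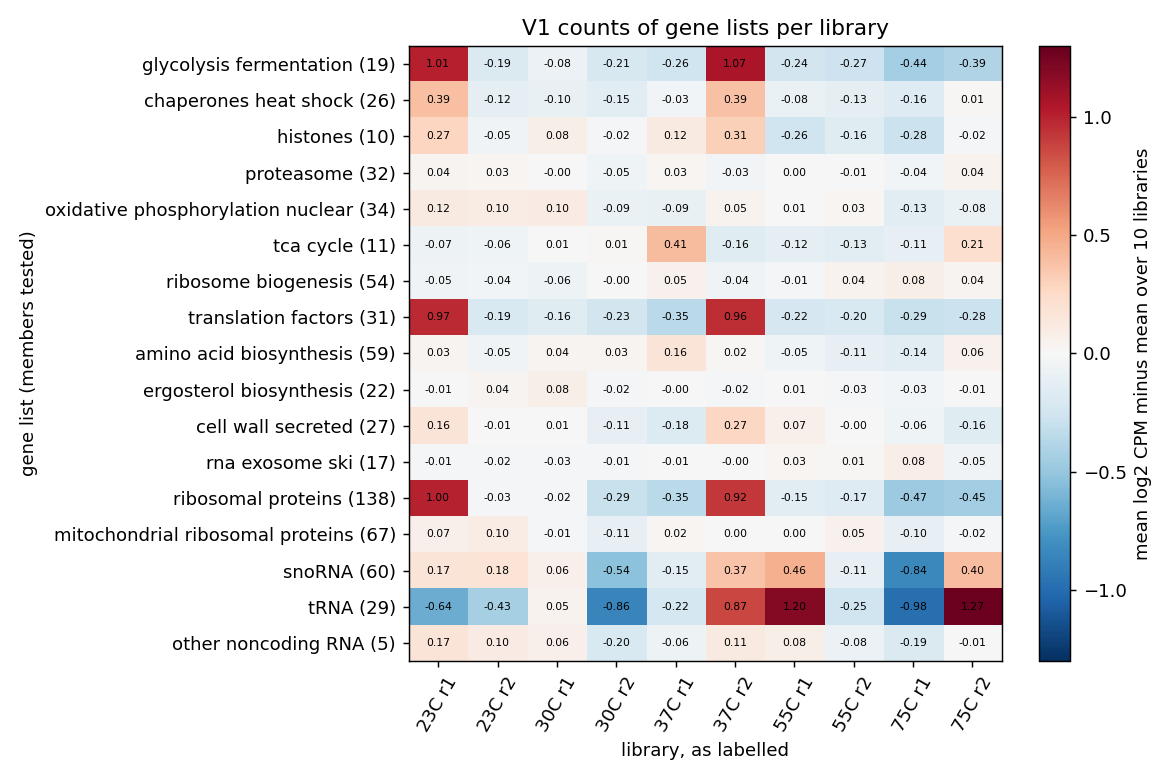
Mean log2 CPM of each of 17 gene lists (rows, members tested in brackets) in each of the 10 libraries as labelled (columns), given as the difference from the list's mean over the libraries, as colour and number. Ribosomal proteins stand at 0.999 and 0.924 in 23 °C replicate 1 and 37 °C replicate 2, and at or below -0.02 in the other 8 libraries.

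A set of genes, among them genes with a near-identical copy, set these 2 libraries apart. TEF2, which with TEF1 encodes translation elongation factor 1 alpha, had 23733 CPM in 23 °C replicate 1 and 19058 CPM in 37 °C replicate 2, against 32.9 to 78.3 CPM in the other 8 libraries. TDH1, a glyceraldehyde-phosphate dehydrogenase gene, had 11593 and 12444 CPM against 30.9 to 51.2 CPM, and EFT1, of elongation factor 2, had 6787 and 7078 CPM against 65.3 to 102 CPM. Of the 38 mRNAs whose highest library exceeded their median by over 8-fold, 37 had these libraries as their highest pair. By gene name, 21 of the 38 are ribosomal protein genes with 2 copies. The others were not scored by copy, among them USA1 with 711 and 814 CPM against 50.8 to 79.3 CPM. TDH1 was not compared with another gene. Over the aligned positions of TEF1 and TEF2, 1424 and 1440 had counts in these 2 libraries, against 104 to 128 in the other 8. TEF1, TEF2, SSB1 and the duplicated ribosomal protein genes are therefore uncertain in every comparison. Shared reads may be repeated in these 2 libraries and missing from the other 8. These genes were chosen after their values were seen.

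**Figure D3:**
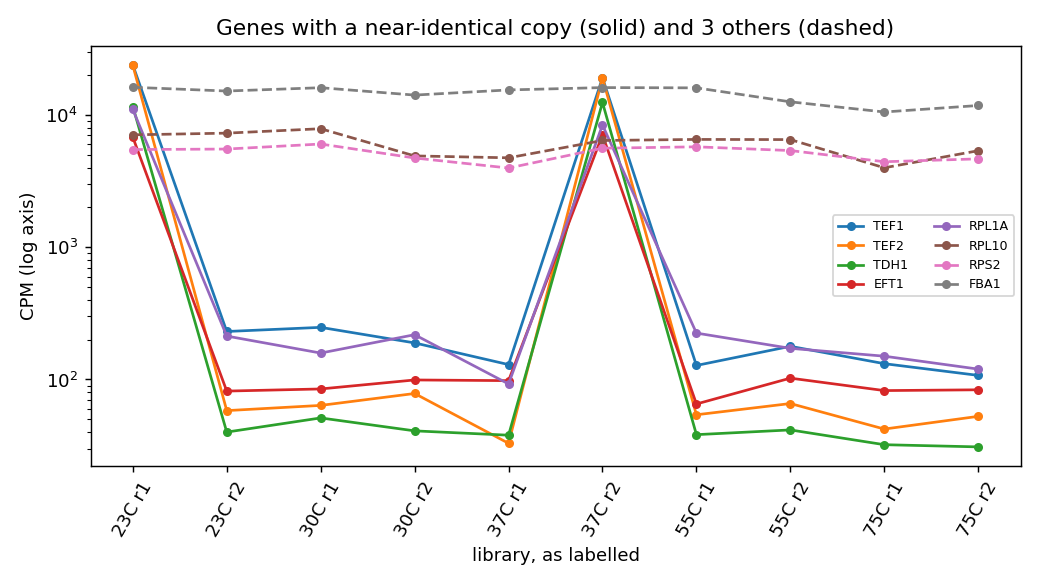
CPM on a log axis in each of the 10 libraries as labelled. Solid lines show TEF1, TEF2, EFT1 and RPL1A, which have a near-identical copy, and TDH1, which was not compared with another gene. Dashed lines show RPL10, RPS2 and FBA1. TEF2 reads 23733 and 19058 CPM in 23 °C replicate 1 and 37 °C replicate 2 and at most 78.3 CPM elsewhere.

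Shares of RNA classes asked whether coding and noncoding RNA were cut alike across the temperatures. Messenger RNA held 67.1% ± 6.4 (SD, n = 10) of the counts and rRNA, which remained after poly(A) selection, 30.7% ± 6.3. The mRNA and rRNA shares make up nearly all counts, so their correlations mirror each other and are not separate results. Cutting cannot be told apart here from the amount of rRNA left after selection. Reads counted in more than 1 gene copy in 23 °C replicate 1 and 37 °C replicate 2 would raise the mRNA share there. The mRNA share was 77.7% and 71.9% in the libraries labelled 23 °C and 65.1% and 56.6% in those labelled 75 °C, and the rRNA share was 20.6% and 25.9% against 33% and 40.8%. With the labelled temperature, the mRNA share had r = -0.738 (permutation p = 0.0164, adjusted p = 0.0383 over 6 classes; rho = -0.739, permutation p = 0.0218). The rRNA share had r = 0.728 (permutation p = 0.0191, adjusted p = 0.0383; rho = 0.739, permutation p = 0.0218). The snRNA share, of 0.0071% ± 0.0027, had r = 0.697 (permutation p = 0.00682, adjusted p = 0.0383; rho = 0.739, permutation p = 0.0225). It was 0.0144% in 75 °C replicate 2, where snR6 had 54.2 CPM, but 0.00673% in 75 °C replicate 1, where snR6 had 4.39 CPM, against 0.00475% and 0.00660% at 23 °C. Transfer RNA, snoRNA and all other entries, at 0.0982% ± 0.0745, 0.0924% ± 0.0223 and 2.05% ± 0.35, had r of 0.336, 0.0742 and 0.420 (rho of 0.246, 0.123 and 0.419) with permutation p of 0.341, 0.835 and 0.226 (0.507, 0.752 and 0.238 for rho). The 2 libraries farthest from the median temperature are both those labelled 75 °C, so leaving them out narrows the range to 23 to 55 °C. Without them, r was -0.699 for mRNA, 0.656 for rRNA and 0.774 for snRNA. The exact permutation adjusted p were 0.111, 0.123 and 0.075, so none of the 3 passed with those 8 libraries. The 3 calls were also lost without 23 °C replicate 1 together with 37 °C replicate 2 (exact permutation adjusted p = 0.142), and without any 1 of 23 °C replicate 1, 30 °C replicate 1 or 2, 37 °C replicate 2, 55 °C replicate 1 or 2 or 75 °C replicate 2. Without 23 °C replicate 2 only the snRNA call was kept. With each library left out in turn, r of the mRNA share ran from -0.864 (without 37 °C replicate 1) to -0.619 (without 75 °C replicate 2). It was -0.693 without 23 °C replicate 1 together with 37 °C replicate 2. Splitting all other entries into 3 classes, as was done after the file was seen, put the adjusted p at 0.0510 for each of the 3. Without the 100 positions with the most counts, r was -0.908 for mRNA and 0.918 for rRNA (permutation p = 1e-05, the smallest that these permutations can give). There, rRNA shares were 12.1% and 15.4% at 23 °C and 24.5% and 29.7% at 75 °C. This setting was not repeated without 23 °C replicate 1 and 37 °C replicate 2.

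**Figure D4:**
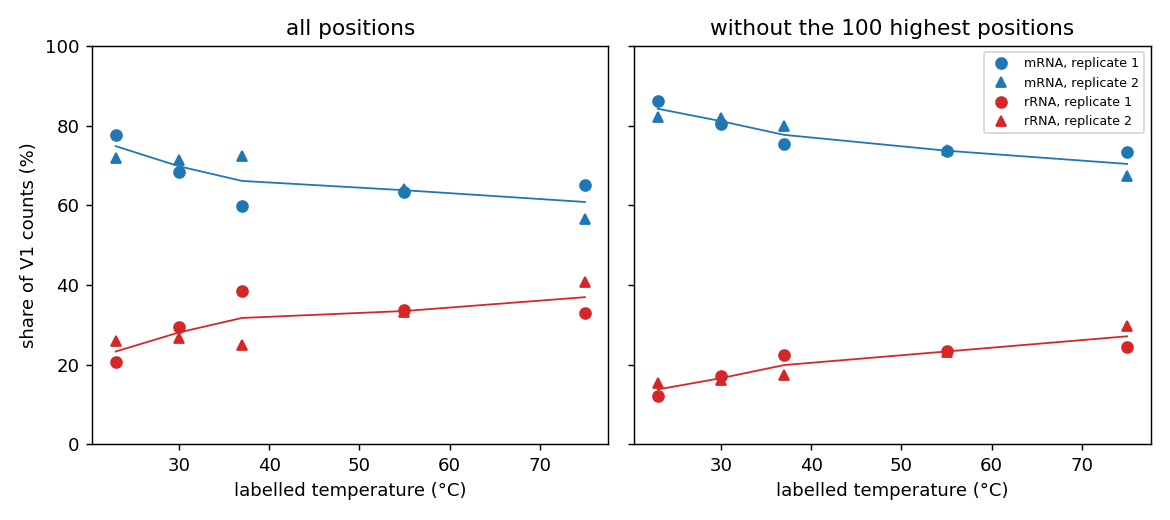
Share of V1 counts in percent against labelled temperature in °C for mRNA (blue) and rRNA (red), with circles for replicate 1, triangles for replicate 2 and lines through the means, over all positions (left) and without the 100 positions with the most counts (right). The rRNA share runs from 20.6% to 40.8% on the left and from 12.1% to 29.7% on the right.

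Codon positions asked whether cutting in coding sequence kept a period of 3 nt. In the 274 mRNA entries whose length equals the coding length of the reference, position 1 of the codon held 30.3% ± 0.7 (SD, n = 10) of the counts, position 2 held 35.7% ± 0.6 and position 3 held 34.0% ± 1.1. Position 1 was the lowest of the 3 in each of the 10 libraries, at 28.7% to 30.9%. With the labelled temperature the 3 shares had r of 0.107, -0.0275 and -0.0498 and rho of 0.123, -0.123 and 0.295. The permutation p were 0.786, 0.940 and 0.898 for r and 0.753, 0.753 and 0.420 for rho, with an adjusted p of 0.940 for each r. Without the 2 libraries farthest from the median temperature r was -0.296, -0.0845 and 0.217. With each transcript weighted equally, r was -0.606, 0.424 and 0.0502 (permutation p of 0.0632, 0.221 and 0.891, adjusted p of 0.190, 0.331 and 0.891) and rho -0.739, 0.271 and 0.197 (permutation p of 0.0212, 0.460 and 0.601), so r changed sign with the weighting for positions 1, 2 and 3, and rho for positions 1 and 2. At the ends of 4471 mRNAs, a measure added after the file was seen, the median density of cuts in the first 100 nt lay at -1.09 ± 0.41 (SD, n = 10) on the log2 scale relative to the rest of the mRNA, and in the last 100 nt at -2.17 ± 0.21. These had r of -0.141 and 0.0532 with the labelled temperature (permutation p of 0.709 and 0.893, both with an adjusted p of 0.893; rho of 0.0739 and 0.0985 with permutation p of 0.861 and 0.810), and r of 0.255 and 0.0832 without the 2 farthest libraries. Counts mark where sequenced fragments start, and a loss of short fragments near the ends was not tested for. The low densities there cannot be read as less pairing.

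Windows of 50 nt, each set against the total of its own transcript, asked which parts of an RNA gained or lost cuts with the labelled temperature. Of 101875 windows on 4617 transcripts, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, with 16288 at an unadjusted p under 0.05 and a smallest adjusted p of 0.185; no other tool was run on windows. Windows of 20 nt and of 100 nt gave 0 calls as well, with 22860 and 9889 windows at an unadjusted p under 0.05. The coefficient of variation between libraries was 0.482 for windows of 50 nt. On simulated windows with a coefficient of 0.3, 74.3% of those changed 4-fold and 9% of those changed 2-fold were found, and the larger spread of the real windows was not simulated.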

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

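The tests in this part were chosen after the values they measure had been seen, except the totals of the 6 entries that match no yeast gene. These entries stand outside the comparisons, and what they are is not given in the sources used here. HA479 held 258841 counts over the 10 libraries, HA5 held 586117, HA704 held 819416, HT held 1550088, p4 held 1132253 and p9 held 59267. Entry p9 ranged from 1777 counts in 75 °C replicate 1 to 20985 in 75 °C replicate 2.

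Most libraries were closest to a library of another labelled temperature, 55 °C replicate 1 being closest to its own replicate. Shared reads in the gene copies of 2 libraries do not enter r between the other 8. Ranks among those 8 therefore cannot test shared reads as the source of the pairing. Positions were still kept by their total over all 10 libraries. Without those 2 libraries, the other 4 pairs of columns 5 apart ranked 2 among all pairings of the remaining 8. They also ranked 2 on mRNA, rRNA and entries without a match, but 21 on tRNA. The test drops 23 °C replicate 1 with 37 °C replicate 2, so it cannot speak to shared reads for that pair. On rRNA positions, 23 °C replicate 1 was closer to 23 °C replicate 2 (r = 0.966) than to 37 °C replicate 2 (r = 0.911). On entries without a match these r were 0.936 and 0.845. Over all positions, columns 5 apart (23 °C replicate 1 with 37 °C replicate 2, and so on) ranked 2 of the 945 ways to form 5 pairs (mean r 0.808) and the labelled pairs 237 (0.50), which restates the pattern; the best (0.817) kept the labelled 55 °C pair. By class, columns 5 apart ranked 2 (mRNA), 11 (rRNA), 240 (tRNA) and 10 (entries without a yeast match) and the labelled pairs 227, 173, 256 and 302, and with untransformed counts columns 5 apart ranked 6, and by depth 82. Labels that do not match the columns and the labelled temperature, whose effect may be graded, thus both stay open by the bounds set. Neither worst rank (240 and 302) decides, and the rank of 240 rests on 158 tRNA positions. On mRNA, rRNA and entries without a match, columns 5 apart ranked no worse than 11 and the labelled pairs no better than 173. On those positions the labelled pairs, as a set, were thus not the most alike libraries. If labels and columns do not match, every comparison by labelled temperature above is affected. An earlier rule, a rank in the top 47 over all positions, had spoken for the mismatch and against the labelled temperature, and was replaced after the ranks were known. The rRNA share outside the 100 highest positions, by contrast, followed the labels (r = 0.918), and within each run of 5 columns it also ran from low to high apart from single steps (12.1%, 15.4%, 17.1%, 16.1%, 22.4% and 17.4%, 23.4%, 23.2%, 24.5%, 29.7%), so it leaves both readings open; no comparison was made under another assignment.

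The excess of gene copies in 23 °C replicate 1 and 37 °C replicate 2 is argued against as a higher level of ribosomal protein mRNAs, since the 19 1-copy ribosomal protein genes had a median deviation of at most 0.0975 log2 units there. Single genes lay higher, RPS31 having 8382 and 8130 CPM against 2783 to 5420 CPM in the other 8 libraries. Copies were assigned by gene name, so sequence that a 1-copy gene shares with other genes was not looked for. The median of the 2-copy genes stood above that of the 1-copy genes by at least 0.571 log2 units in both libraries and by at most 0.0327 in the other 8. In TEF1 and TEF2, 93.4% and 92.7% of positions with counts had equal counts in these libraries, against 6.50% to 18.3% in the others. These values rest on 1424 and 1440 positions in these libraries, but on only 104 to 128 in the others. For EFT1 and EFT2 the positions were 2401 and 2462 against 174 to 214. The percentages were 93.5% and 93.3% in EFT1 and EFT2, 77.0% and 77.4% in RPL1A and RPL1B, and 46.7% and 47.7% in TDH2 and TDH3, against at most 22.8%, 11.1% and 8.71% in the others. Reads shared between near-identical copies, counted in each copy in these libraries and largely missing from the others, may therefore account for the excess.

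The transcripts that rose with the labelled temperature were long. Over 4558 mRNAs the slope and the length had a Spearman rho of 0.393 across genes, which are not independent replicates. A transcript length bias between libraries is a candidate explanation. This rho restates the pattern, so it cannot tell such a bias from an effect of temperature on long mRNAs. The deviation of each library correlated with length from -0.39 in 23 °C replicate 2 to 0.49 in 75 °C replicate 1. A difference between the first 5 and the last 5 columns cannot be told apart from the labelled temperature: 73.6% of the 121 called transcripts (89) differed between 37 °C replicate 2 and replicate 1 in the direction of their slope, between the bounds set for either outcome. The labelled temperature itself stays open as a biological explanation.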

How the results depend on the processing

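Leaving out 23 °C replicate 1 together with 37 °C replicate 2, splitting the class of other entries, leaving out the farthest libraries for codon shares and the use of the entries without a yeast match as controls were chosen after seeing the data; the other settings were planned. The cause of each change below was not tested. For 75 °C against 23 °C, the count of 0 became 314 with DESeq2's Wald test and 74 under scaling to the entries without a yeast match, and ranged from 0 to 2 with each library left out in turn. For the steps, that scaling gave 35 (30 °C against 23 °C), 11 (37 °C against 30 °C) and 24 (55 °C against 37 °C), and DESeq2's Wald test gave 5 and 1 for the latter pair; leaving out each library gave 0, 0 to 1, 0 to 129 and 0 to 1, and leaving out both libraries with the excess gave 19 for 55 °C against 37 °C. The slope's count of 121 became 0 with total-count scaling, 0 with scaling to the entries without a match, 492 with DESeq2's Wald test, 0 without both libraries with the excess, and 0 to 411 with each library left out; DESeq2 size factors (129) and mRNAs alone (149) stayed within 1.5 times, and leaving out the filter, which removed no transcript, is the same fit (121). With the replicate block the slope's count was 64, and the pairwise tests stayed at 0; same-numbered libraries did not deviate together (r of deviations from -0.706 to 0.0320, 0 of 10 over 0.1), so the number gives no pairing. Of 4 gene lists, 0 held with an estimated correlation, 3 held without both libraries with the excess, and each library left out gave 1 to 7. Of 3 class shares, 0 held with the replicate block, 0 without the 2 libraries farthest from the median temperature, 0 without both libraries with the excess and 0 with the other class split, and 0 to 3 with each library left out. Codon shares and windows stayed at 0 calls in every setting run. Agreement over untransformed positions was 0.691 within and 0.631 between labelled temperatures, and 0.690 and 0.630 with 10 or more counts. Shares by untranslated region and start and stop profiles, with their alternatives, were not run. With 2 libraries per temperature, a test without 1 of them assumes that the lone library varies like the other groups.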

Other observations

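Single positions of rRNA are given in percent of the counts of their own entry. They were taken, after the values were seen, from the positions with the most counts over all libraries, and not all of those are described. Positions 516 and 515 of RDN25-1, which have more counts than most of them, ran from 1.40% to 8.04% and from 1.23% to 5.79%. Position 56 of RDN58-1, the short rRNA that pairs with the large-subunit rRNA, held 30.9% of its counts in 37 °C replicate 1 and 19.5% in 75 °C replicate 2. It held 18.1% in 30 °C replicate 2 and 12.5% in 75 °C replicate 1, against 2.40% to 4.61% in the other 6 libraries. By columns 5 apart, 37 °C replicate 1 pairs with 75 °C replicate 2, and 30 °C replicate 2 with 75 °C replicate 1. Position 435 of RDN25-1, the large-subunit rRNA, held 16.3% in 30 °C replicate 1 and 1.0% and 0.362% in 37 °C replicate 1 and 75 °C replicate 2. Position 3325 of RDN25-1 held 0.0171% and 0.0807% in 37 °C replicate 1 and 75 °C replicate 2, against 0.843% to 3.28% in the others. Position 59 of RDN5-1 held 54.0% in 55 °C replicate 2 and 11.6% in 37 °C replicate 1. Positions 1403 and 1404 of RDN18-1, the small-subunit rRNA, held 8.72% and 6.75% in 75 °C replicate 2 and no more than 3.68% each in the other 9 libraries.

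Of the noncoding RNAs, snR6 is given by library, and TLC1 and SCR1 as a mean over the 10 libraries. The spliceosomal snRNA snR6 had 54.2 CPM in 75 °C replicate 2, 4.39 CPM in 75 °C replicate 1 and 2.01 to 8.85 CPM in the other 8 libraries. The telomerase RNA TLC1 had 89.6 ± 4.8 CPM (SD, n = 10) and the signal recognition particle RNA SCR1 had 398 ± 109 CPM.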
